A study of Homo sapiens with 30 samples.

How the data were processed

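Human tRNA was measured by multiplex small RNA sequencing (MSR-seq) in 30 libraries of HEK293 cells, 3 replicates in each of 10 groups: 5 mistranslation reporters, each alone and with its missense-correcting tRNA (mc-tRNA). Groups and replicate numbers were taken from the sample labels. The labels call the replicates independent.

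The deposited tables hold whole-number counts per reference sequence, per the file headers and the values, in a version of all read lengths and a version whose name carries 60 and 200. Counting was done by the authors before deposit. The submitters' processing notes name FastQC, Bowtie2 and SAMtools, without versions, and the human build hg38. The counting program, the reference set, the treatment of reads that fit several references, the length filter and any use of molecular identifiers are not given in the sources used here, so counts were treated as reads and intervals were not computed from them as if each were a molecule. The reference names are those of the deposited tables, and 9 of 11 references that are not tRNA were matched to a symbol by accession.

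The deposited per-position tables give the pileup and the counts of each base as counts, and a mutation fraction, per the file headers. That fraction, as the authors deposited it, equalled mismatching bases over pileup within 0.0011 at 99.94% of positions with at least 20 reads. It was 1 at 17811 positions whose reference base is in lower case and where most reads match, so mismatch was recomputed here from the base counts. A score for reverse-transcription stops in the same deposited tables was not used, and insertions and deletions were not analysed.

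Abundance was tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts of tRNA references, with TMM scaling. References needed at least 10 counts in at least 3 of the 30 libraries, which left 266 of 288. The 11 references that are not tRNA were not part of this test. A fit of all 10 group means gave 5 contrasts of mc-tRNA against reporter alone within a reporter, their mean, and an F-test over 4 contrasts for the difference among reporters. The fit had 20 residual degrees of freedom and a common biological coefficient of variation of 0.262. P-values were adjusted by Benjamini-Hochberg within a contrast at a threshold of 0.05. All tests are two-sided, except Fisher's exact test for shared calls, which is one-sided for an excess. Levels are given as TMM-scaled CPM. The SE printed with an abundance fold change is its absolute log2 value divided by the square root of its F statistic. It was derived from the test and is not an estimate taken from the fit.

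Mismatch at a position was tested with limma 3.58.1 (eBayes with trend) on the log2 ratio of mismatch to reference-base reads, each plus 0.5. Positions needed at least 100 reads in every library and a mean mismatch of at least 10%, which left 282, and mc-tRNA references were left out of this test. The mismatch of an mc-tRNA was set beside that of its parent tRNA in the same libraries, without a test, at positions outside the anticodon with at least 100 reads and at least 10% mismatch in either; the lowest coverage there was 14241 reads for an mc-tRNA and 361 for a parent. Positions count from 1 at the 5′ end of the reference, and standard tRNA positions were assigned from the reference sequence.

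Lists were tested with limma's camera on voom values with a preset correlation of 0.01, and again with a correlation estimated per list. The 31 lists were mitochondrial tRNAs, cytosolic tRNAs, initiator methionine, selenocysteine, tRNAs with A at position 34, tRNAs with a long variable arm, 20 amino acids, and the 5 anticodons of the mc-tRNAs. Counts adjusted over the list alone come from the same edgeR p-values. Positions were also grouped by the modified site they correspond to. Counts of other RNA were compared with exact permutation tests, in which 3 against 3 libraries cannot give a p under 0.1.

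The tests, the lists, the alternatives and the rule for the tRNAs named in the text were fixed before the data were examined. Per reporter the rule takes the mc-tRNA, up to 5 endogenous tRNAs with its anticodon by mean count, the 5 of the amino acid family of its body with the smallest adjusted p, and the 8 largest rises and 8 largest falls among the others past the threshold whose 3 libraries with the mc-tRNA all lie above, or all below, the 3 without; where none pass, it takes the 3 smallest p-values. For the mean it takes the 10 largest rises and falls past the threshold with the same sign in all 5 reporters, and for positions the 5 largest rises and 5 largest falls past the threshold, or else the 3 smallest p-values.

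The alternatives tried for abundance were DESeq2 1.42.0 with its size factors, library totals, no filter, a mean of at least 100 counts, the 60 to 200 tables, all references, leaving out the mc-tRNA and its body, sums per anticodon, the 6 libraries of a reporter alone, the replicate number as a block and leaving out each library. For positions they were coverage minimums of 20 and 500 reads, mismatch minimums of 5% and 20%, the 60 to 200 tables and edgeR on mismatch and reference-base counts, with the same fits of 6 libraries, blocks and left-out libraries. Added after the data were seen were fits without the 3 libraries with over 15% of counts on other RNA, the parent tRNA from the reporter-alone libraries, the block for lists, and lists tested against endogenous tRNAs only, since the comparison set of each list otherwise holds the 5 mc-tRNAs.

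Replicate numbers in the labels could pair a reporter-alone library with an mc-tRNA library. Over all tRNAs, deviations of same-numbered libraries from their group means correlated at 0.36, 0.28 and 0.57 in R96W, and in the other reporters at least 1 pair lay under 0.1. The labels state no shared day or batch, so the pairing in R96W comes from the data alone, and blocked values are given for R96W where they change a call. Replicates of a group differed by more than sampling noise, with a lowest chi-square over degrees of freedom of 22.6 among 30 replicate pairs, so none was treated as a second deposit of the same library. This does not tell separate cultures from repeated library preparation, for which the labels are the only source.

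The tests were checked on simulated data with the means and library sizes of the real libraries, 5 simulations each. Of 261 tRNAs 40 were changed per simulation, because the tables hold too few references for more. With a 2-fold change 72.3% were recovered in R65, 75.4% in R96Q, 60% in R96C, 69.2% in R96H and 70.8% in R96W. With a 1.5-fold change it was 25.7%, 28.6%, 31.4%, 30% and 20%, and with a 4-fold change 95.4%, 90.8%, 92.3%, 89.2% and 92.3%. Of unchanged tRNAs 0.36% to 0.72% were called. Simulated tRNAs and positions were drawn independently, without deviations shared by a whole library. A split of the real R96W libraries that mixes the groups called 90 tRNAs, so the simulated rate does not describe false calls in the real data. Of 282 positions 30 were changed, and a log2 odds of 1 was recovered in 90.7%, 85.3%, 82.7%, 88% and 90.7%, and of 0.5 in 60%, 45.3%, 54.7%, 57.3% and 48%, in the same order of reporters. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.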

Results

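Missense-correcting tRNAs (mc-tRNAs) are engineered transfer RNAs whose anticodon has been changed so that they read the codon of another amino acid. Their amounts, the mismatch signatures of their modified bases and the amounts of the endogenous tRNAs around them were measured here in HEK293 cells, a human embryonic kidney cell line. The 5 mistranslation reporters, fusions of a mutant EGFP to mCherry, are called R65, R96Q, R96C, R96H and R96W after the EGFP residue. Cells received 1 of them, either alone or together with the matching mc-tRNA. mCherry-positive cells were sorted 48 h after transfection, and 1 µg of total RNA was sequenced by multiplex small RNA sequencing (MSR-seq). In this library method bases whose modification disturbs pairing leave mismatches in the reads. Each of the 10 groups held 3 replicates that the labels call independent, 30 libraries in all. Total counts over 299 reference sequences ran from 270140 in R96C with the mc-tRNA, replicate 3, to 4632308 in R96C reporter alone, replicate 3.

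The R65 mc-tRNA, mc-Ser-tRNA_Arg(CCG), has the body of tRNA-Ser-CGA-1-1 with G35C and A36G, counting positions from 1 at the 5′ end of the reference. The other 4 have the body of tRNA-Arg-CCT-4-1. Of these, mc-Arg-tRNA_Gln(CTG) for R96Q carries C35T and T36G and mc-Arg-tRNA_Cys(GCA) for R96C carries C34G and T36A. mc-Arg-tRNA_His(GTG) for R96H carries C34G, C35T and T36G and mc-Arg-tRNA_Trp(CCA) for R96W carries T36A. Because these references differ from an endogenous tRNA in 1 to 3 bases, and many human tRNA genes differ from each other in as few, a count on one reference can include reads of a near-identical one. Each comparison below is between the libraries with the mc-tRNA and the reporter-alone libraries of the same reporter. By their deposited names the reporter-alone and mc-tRNA libraries carry different inline barcodes in every pool, so that barcode and group cannot be told apart.

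Counts on RNA other than tRNA made up 3.18% and 3.77% of the R65 libraries without and with the mc-tRNA, 5.60% and 4.34% in R96Q. They made up 6.81% ± 2.65 and 12.2% ± 7.14 (SD, n = 3) in R96C, 5.65% and 5.06% in R96H, and 19.7% ± 18.0 and 18.6% ± 24.0 in R96W. The 3 libraries above 15% were R96C with the mc-tRNA, replicate 3 (18.7%), R96W reporter alone, replicate 3 (40.3%), and R96W with the mc-tRNA, replicate 3 (46.3%). Counts of changed tRNAs are therefore also given without these 3 libraries, a limit chosen after the data were seen.

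The first question was how much of each mc-tRNA the cells held. In libraries with the mc-tRNA, mc-Arg-tRNA_Cys(GCA) took 16.9% ± 1.83 (SD, n = 3) of all tRNA counts, mc-Arg-tRNA_Trp(CCA) 14.2% ± 3.95, mc-Arg-tRNA_Gln(CTG) 11.8% ± 1.12, mc-Ser-tRNA_Arg(CCG) 7.70% ± 0.574 and mc-Arg-tRNA_His(GTG) 4.88% ± 0.194. The first 4 were the most abundant tRNA reference of their libraries, and mc-Arg-tRNA_His(GTG) ranked 3. In the matching reporter-alone libraries the shares were 0.258% ± 0.0684, 0.824% ± 0.445, 0.743% ± 0.384, 0.0465% ± 0.0073 and 0.118% ± 0.0321, in the same order. Of these reporter-alone counts 6.74% to 44.7% remained in the 60 to 200 tables, against 77.7% to 99.5% of the counts of the same mc-tRNA in the libraries that received it. All 5 mc-tRNAs rose, and every library with the mc-tRNA lay above every library without it.

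The fitted log2 fold changes were 7.42 (SE 0.47, adjusted p = 4.75e-12) for mc-Ser-tRNA_Arg(CCG), 4.15 (SE 0.53, adjusted p = 1.20e-05) for mc-Arg-tRNA_Gln(CTG) and 6.34 (SE 0.68, adjusted p = 2.66e-07) for mc-Arg-tRNA_Cys(GCA). They were 5.47 (SE 0.45, adjusted p = 4.10e-09) for mc-Arg-tRNA_His(GTG) and 4.43 (SE 0.44, adjusted p = 1.18e-07) for mc-Arg-tRNA_Trp(CCA). In the count table that by its name keeps reads of 60 to 200, they were 8.88, 7.47, 9.11, 7.75 and 7.43, with 0.0164% to 0.0947% of tRNA counts in the reporter-alone libraries. Among reads on an mc-tRNA and its parent reference together that cross the first changed anticodon base, 88.1% to 99.6% carried the mc-tRNA base in libraries with the mc-tRNA and 10.9% to 76.0% in those without. The log2 ratio of these percentages was 0.45, 0.71, 1.53, 2.58 and 0.82 for R65, R96Q, R96C, R96H and R96W, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow.

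**Figure D1:**
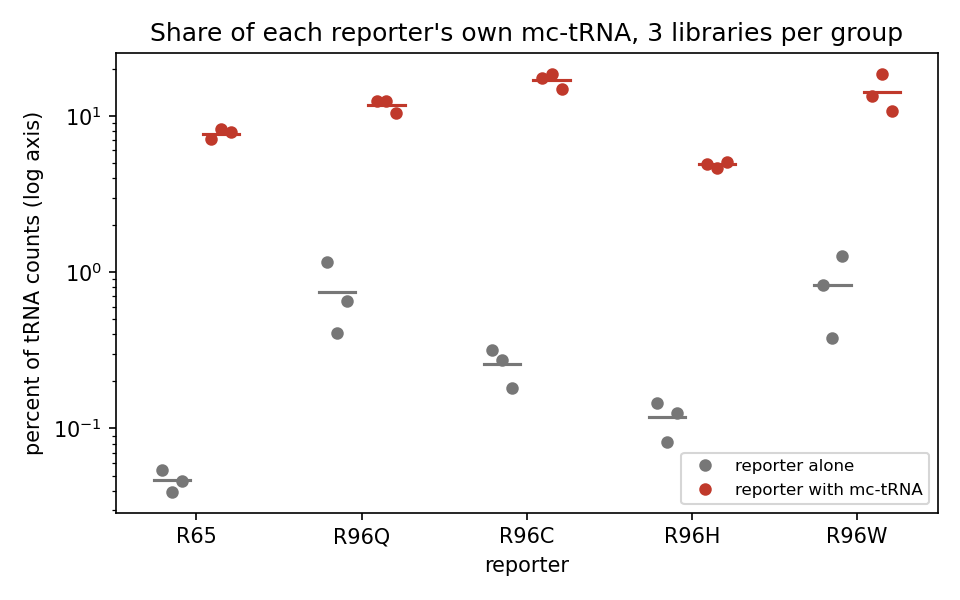
Percent of all tRNA counts on each mc-tRNA reference (log axis) in the 3 reporter-alone and the 3 mc-tRNA libraries of its reporter; points are libraries and lines are means. With the mc-tRNA the means lie between 4.88% and 16.9%, and without it between 0.0465% and 0.824%.

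The second question was whether the mc-tRNAs carry the mismatch signatures of the tRNA they were built from. At C32, the anticodon-loop base that carries 3-methylcytidine in human arginine, serine and threonine tRNAs, the arginine-bodied mc-tRNAs had far fewer mismatches than the tRNA they were built from. The mismatch level was 0.387% ± 0.0367 in mc-Arg-tRNA_Gln(CTG), 0.607% ± 0.0402 in mc-Arg-tRNA_Cys(GCA), 1.54% ± 0.19 in mc-Arg-tRNA_Trp(CCA) and 9.73% ± 0.594 in mc-Arg-tRNA_His(GTG) (SD, n = 3). In the same libraries endogenous tRNA-Arg-CCT-4-1 stood at 87.7% ± 1.81, 81.9% ± 4.19, 85.9% ± 7.14 and 93.1% ± 2.20.

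At A58, the T-loop base that carries 1-methyladenosine, the 4 mc-tRNAs for R96Q, R96C, R96H and R96W reached 96.8%, 94.7%, 95.6% and 95.1% mismatch. tRNA-Arg-CCT-4-1 stood at 88.0%, 82.5%, 92.7% and 89.1% in the same libraries and at 94.1%, 94.1%, 95.1% and 93.6% in the reporter-alone libraries. At G9, a site of 1-methylguanosine, the mc-tRNAs showed 33.2%, 39.4%, 40.9% and 34.4% and the endogenous tRNA 31.8%, 27.3%, 33.99% and 32.9%. At G7 the values were 4.81%, 8.47%, 7.56% and 5.96% against 18.4%, 15.8%, 22.1% and 21.4%.

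The serine-bodied mc-Ser-tRNA_Arg(CCG) had 84.2% mismatch at G26, a site of dimethylguanosine, against 79.9% in tRNA-Ser-CGA-1-1 of the same libraries, and 59.0% against 44.4% at the A in reference position 67, which is standard position 58. Its C32 stood at 14.2% ± 0.258 and its variable-arm C at position 50 at 38.1% ± 3.11, where tRNA-Ser-CGA-1-1 had 21.1% ± 0.326 and 29.5%. In the R65 reporter-alone libraries tRNA-Ser-CGA-1-1 had 83.6% ± 4.44 at C32 and 89.1% at position 50. In the libraries with the mc-tRNA, however, 79.4% of the reads on tRNA-Ser-CGA-1-1 carried the base of the mc-tRNA at position 35, so its value there is not that of the endogenous tRNA alone.

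Over the 4 sites compared per reporter, the median difference between the mc-tRNA and its parent reference in the same library was 6.42 points (SD 1.01) for R65, -6.09 (SD 1.97) for R96Q, 2.37 (SD 2.05) for R96C, -5.80 (SD 0.842) for R96H and -6.96 (SD 3.94) for R96W. These differences were left untested, as planned, and the R65 value mostly sets mc-tRNA reads against mc-tRNA reads. The R96C median fell to -0.032 without replicate 3 of the mc-tRNA libraries. Against the endogenous tRNA of the reporter-alone libraries, a comparison chosen after the data were seen, the medians for R65 and R96C were -26.5 and -4.76.

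**Figure D2:**
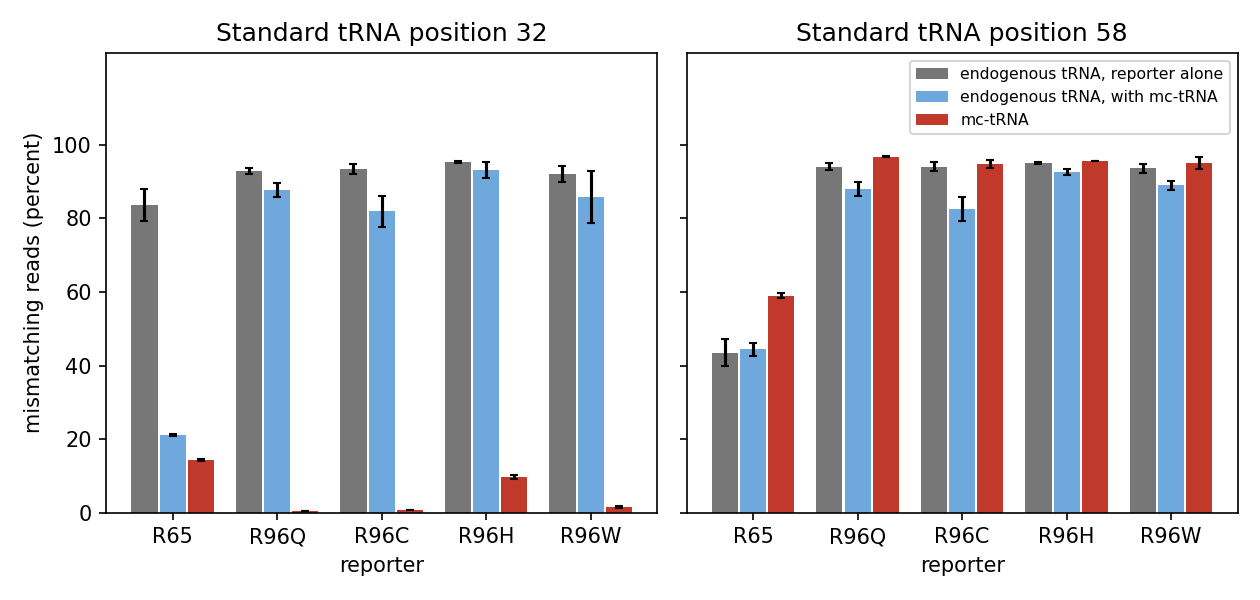
Percent of reads with a mismatch at standard tRNA positions 32 and 58 of each mc-tRNA and of its endogenous parent, the latter in the reporter-alone libraries and in the libraries with the mc-tRNA. Bars are means and whiskers SD over 3 libraries. In R65 with the mc-tRNA the parent reference holds 79.4% of reads with the mc-tRNA base. At C32 the arginine-bodied mc-tRNAs lie between 0.387% and 9.73% and tRNA-Arg-CCT-4-1 of the same libraries between 81.9% and 93.1%.

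The third question was whether an mc-tRNA alters the other tRNAs of the cell. Of 266 tRNA references with enough counts, 261 were endogenous, 239 cytosolic and 22 mitochondrial. Levels below are TMM-scaled CPM (counts scaled to a common library size) with SD over 3 libraries. Fold changes depend on the scaling, because the mc-tRNA itself takes up to 18.5% of the tRNA counts of a library. With TMM the median log2 fold change of the endogenous tRNAs was -0.11 in R65, -0.02 in R96Q, -0.01 in R96C, -0.06 in R96H, 0.10 in R96W and 0.00 in the mean of the reporters. Scaling by library totals moved it to -0.18, -0.19, -0.32, -0.14, -0.17 and -0.17, a shift beyond 0.1 in R96Q, R96C, R96W and the mean. DESeq2 size factors gave -0.06, 0.01, 0.07, -0.04, 0.10 and 0.04.

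In R65, tRNAs of the family whose anticodon the mc-tRNA carries fell. tRNA-Arg-CCG-1-1 went from 15500 ± 1560 to 7425 ± 1330 CPM (log2 fold change -1.06, SE 0.21, adjusted p = 0.0016) and tRNA-Arg-CCG-2-1 from 5342 ± 206 to 3471 ± 256 CPM (-0.62, SE 0.16, adjusted p = 0.00793), each lower in 3 of 3 libraries. Of 19 arginine tRNAs 8 fell and none rose, or 9 adjusted over the list alone (median -0.56, camera adjusted p = 0.000593, but adjusted p = 0.611 with an estimated correlation). Beside these, tRNA-Thr-CGT-1-1 fell from 210.1 to 89.3 CPM (-1.23, SE 0.18, adjusted p = 1.94e-05) and tRNA-Asn-GTT-9-1 from 293.5 to 129.1 CPM (-1.18, SE 0.16, adjusted p = 4.63e-06).

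Serine references of the body that the mc-tRNA was built on were higher. tRNA-Ser-CGA-1-1 went from 235.6 ± 5.61 to 3769 ± 281 CPM (log2 fold change 3.999, SE 0.14, adjusted p = 2.25e-17), tRNA-Ser-CGA-2-1 from 92.9 to 790.4 CPM (3.09, adjusted p = 1.13e-12) and tRNA-Ser-CGA-3-1 from 82.4 to 263.2 CPM (1.67, SE 0.30, adjusted p = 0.000423). The share of their reads carrying the mc-tRNA base at position 35 went from 2.32% to 79.4%, from 4.45% to 82.1% and from 0% to 72.7%, so these counts include reads with the sequence of the mc-tRNA. On tRNA-Ser-CGA-4-1 and tRNA-Ser-TGA-4-1 this share went from 0.148% to 15.8% and from 0.459% to 17.9%. tRNA-Ser-TGA-1-1 rose from 396.4 to 670 CPM (0.76, SE 0.19, adjusted p = 0.00784) with 0.148% and 0.875% of such reads, and tRNA-Ser-TGA-3-1 was at 0.53 (adjusted p = 0.186). The serine list of 18 includes these tRNA-Ser-CGA references with mc-tRNA reads and was not tested without them. In this list 4 rose and none fell, and 4 rose adjusted over the list alone. Its test was upward (camera adjusted p = 0.00129, but adjusted p = 0.771 with an estimated correlation) with a mean of 0.53, while its median was -0.00 (-0.05 under library totals and 0.05 with DESeq2 size factors).

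The 31 called endogenous tRNAs of R65 were 8 that rose, 3 of them the tRNA-Ser-CGA references with mc-tRNA reads, and 23 that fell, with 53 at an unadjusted p under 0.05. The largest other rises were mt-tRNA-Gln-TTG (0.70, SE 0.22, adjusted p = 0.0388), tRNA-Ala-AGC-2-1 (0.44), tRNA-Ala-TGC-3-1 (0.43) and tRNA-Ala-CGC-2-1 (0.37). Each lost its call in 3 to 5 of the 6 fits that left out 1 library. The adjusted p went up to 0.175, 0.241 and 0.197 for the first, second and last without reporter-alone replicate 3, and up to 0.149 for tRNA-Ala-TGC-3-1 without mc-tRNA replicate 1. Falls were led by tRNA-Ala-AGC-10-1 (-2.29, SE 0.53, adjusted p = 0.00455, at 15.04 CPM without the mc-tRNA), tRNA-Leu-TAA-4-1 (-1.59) and tRNA-Ala-AGC-16-1 (-1.34). Next came tRNA-Leu-TAA-2-1 (-1.29, SE 0.28, adjusted p = 0.00287), tRNA-Ala-AGC-13-1 (-1.26) and tRNA-Ala-AGC-12-1 (-1.05). Of 22 mitochondrial tRNAs, 1 rose, none fell and none passed adjusted over the list alone (median 0.59, camera adjusted p = 4.30e-05, but adjusted p = 0.388 with an estimated correlation). The mitochondrial share of tRNA counts was 1.85% ± 0.174 without and 2.78% ± 0.531 with the mc-tRNA (exact two-sided p = 0.1). Of 239 cytosolic tRNAs 7 rose and 23 fell, 30 adjusted over the list alone (median -0.15, camera adjusted p = 7.73e-09, and adjusted p = 0.000419 with an estimated correlation). Its comparison set held the 5 mc-tRNAs beside the mitochondrial tRNAs. Against the latter alone, a comparison chosen after the data were seen, it was at adjusted p = 2.85e-06, and at adjusted p = 0.00379 with an estimated correlation. This is the same comparison as that of the mitochondrial list against cytosolic tRNAs, which was at camera adjusted p = 0.293 with an estimated correlation. Of 13 asparagine tRNAs 2 fell, 3 adjusted over the list alone (median -0.29, camera adjusted p = 0.0116, but adjusted p = 0.423 with an estimated correlation). Both tRNA-Arg-CCG members fell, 2 adjusted over the list alone (median -0.84, camera adjusted p = 0.0387, but adjusted p = 0.388 with an estimated correlation).

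The R65 count was 20 without reporter-alone replicate 2 and 19 without mc-tRNA replicate 2, and 11 of the 18 named tRNAs kept their call whichever library was left out. tRNA-Leu-TAA-4-1 lost it in 2 such fits (adjusted p up to 0.0853, without mc-tRNA replicate 1), tRNA-Ala-AGC-16-1 in 4 (up to 0.188, without mc-tRNA replicate 3) and tRNA-Ala-AGC-12-1 in 1 (0.0885, without mc-tRNA replicate 2). DESeq2 size factors gave 14 rises and 22 falls. Without the 3 libraries rich in other RNA, none of them from R65, the shared fit called 53 (22 rises, 31 falls).

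In R96Q no endogenous tRNA passed the threshold. edgeR and DESeq2 both called 0, with 7 and 6 tRNAs at an unadjusted p under 0.05. The glutamine tRNAs with the anticodon of the mc-tRNA were at log2 fold changes of 0.26 (tRNA-Gln-CTG-1-1, 2336 to 2796 CPM), 0.24 (tRNA-Gln-CTG-2-1, 1822 to 2146 CPM) and 0.07 (tRNA-Gln-CTG-3-1). tRNA-Gln-CTG-4-1 and tRNA-Gln-CTG-6-1 were at 0.17 and 0.33, and all 5 had adjusted p = 0.983. Arginine tRNAs stood at -0.42 (tRNA-Arg-CCT-1-1, 1635 to 1223 CPM, SE 0.15, adjusted p = 0.501), -0.29 (tRNA-Arg-CCT-2-1), -0.25 (tRNA-Arg-CCT-3-1), -0.24 (tRNA-Arg-TCG-2-1) and -0.22 (tRNA-Arg-CCG-2-1), the last 4 at adjusted p = 0.983. Apart from these tRNAs, the smallest p-values belonged to tRNA-Ala-AGC-6-1 (-0.48, adjusted p = 0.528), tRNA-Asn-GTT-5-1 (0.56, adjusted p = 0.528) and tRNA-Ser-GCT-5-1 (-0.36, adjusted p = 0.908).

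None of the 31 tRNA lists passed in R96Q, with a lowest camera adjusted p of 0.0959 for glutamine and for serine. Against endogenous tRNAs only, without the mc-tRNAs, these 2 were called (adjusted p = 0.00504, upward, and 0.0167, downward), but were at adjusted p = 0.774 with an estimated correlation. Scaling by library totals, which shifts all R96Q values downward, called 3 tRNAs and all 3 fell: tRNA-Arg-CCT-1-1 (-0.59, adjusted p = 0.0252), tRNA-Ser-GCT-5-1 (-0.53, adjusted p = 0.0395) and tRNA-Ala-AGC-6-1 (-0.65, adjusted p = 0.0495). Each other setting tried, and each left-out library, also gave 0 calls.

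In R96C, 6 of 15 cysteine and 8 of 19 arginine tRNAs fell. Among cysteine tRNAs, which share the anticodon of this mc-tRNA, tRNA-Cys-GCA-5-1 went from 50.9 to 13.6 CPM (log2 fold change -1.58, SE 0.39, adjusted p = 0.00561) and tRNA-Cys-GCA-11-1 from 54.8 to 20.5 CPM (-1.37, SE 0.34, adjusted p = 0.00577). tRNA-Cys-GCA-4-1 went from 121.3 to 74.6 CPM (-0.72, SE 0.19, adjusted p = 0.010). These falls rest on few reads, with lowest counts of 2, 4 and 19, in this order, in a library with the mc-tRNA. No cysteine tRNA rose, and 8 passed adjusted over the list alone (median -0.90, camera adjusted p = 0.000425, but adjusted p = 0.485 with an estimated correlation). tRNA-Cys-GCA-2-1 stood at -0.90 (SE 0.37, adjusted p = 0.103). Of the arginine tRNAs 9 passed adjusted over the list alone (median -0.40, camera adjusted p = 0.00025, but adjusted p = 0.485 with an estimated correlation). The arginine falls included tRNA-Arg-TCG-2-1 from 4465 ± 66.8 to 1906 ± 294 CPM (-1.23, SE 0.19, adjusted p = 5.24e-05) and tRNA-Arg-TCG-5-1 from 8629 to 3864 CPM (-1.16, SE 0.19, adjusted p = 0.00016). They also included tRNA-Arg-CCG-1-1 from 16710 ± 4750 to 8768 ± 1770 CPM (-0.93, SE 0.21, adjusted p = 0.00329).

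Of 4 phenylalanine tRNAs 2 rose in the same cells. tRNA-Phe-GAA-2-1 went from 172.5 ± 24.6 to 482.7 ± 92.2 CPM (1.49, SE 0.30, adjusted p = 0.000919) and tRNA-Phe-GAA-3-1 from 165 to 455.2 CPM (1.48, SE 0.27, adjusted p = 0.000538). In this list 3 passed adjusted over the list alone (median 1.48, camera adjusted p = 0.00167, but adjusted p = 0.454 with an estimated correlation). tRNA-Val-CAC-2-1 rose from 5478 to 8312 CPM (0.60, SE 0.16, adjusted p = 0.00939). The other leading rises were mt-tRNA-Val-TAC (1.07, adjusted p = 0.0415), mt-tRNA-Gln-TTG (0.81), mt-tRNA-Leu-TAG (0.73), tRNA-Ser-AGA-3-1 (0.71) and tRNA-Gln-CTG-3-1 (0.53). All 5 lost their call under library totals (adjusted p from 0.123 to 0.436), as did tRNA-Val-CAC-2-1 (0.0639). Falls outside the cysteine and arginine families were led by tRNA-Leu-TAA-3-1 (-0.97, SE 0.18, adjusted p = 0.000667) and tRNA-Thr-CGT-1-1 (-0.95, SE 0.19, adjusted p = 0.00085). Next were tRNA-Pro-CGG-2-1 (-0.90), tRNA-Pro-AGG-1-1 (-0.90) and tRNA-Ala-AGC-1-1 (1735 to 952.8 CPM, -0.86, SE 0.16, adjusted p = 0.000533).

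Other lists called in R96C were proline (4 of 7 fell, 5 adjusted over the list alone, median -0.69, camera adjusted p = 0.00434) and alanine (3 of 28 fell and 1 rose, 4 adjusted over the list alone, median -0.20, adjusted p = 0.0326). These were at adjusted p = 0.557 and 0.751 with an estimated correlation. Glutamine (1 of 11 rose, also adjusted over the list alone, median 0.37, adjusted p = 0.0152) and Gln-CTG (1 of 7 rose, 2 adjusted over the list alone, median 0.53, adjusted p = 0.0172) were called upward, but were at adjusted p = 0.565 and 0.557 with an estimated correlation. So was mitochondrial tRNA (3 of 22 rose, 1 adjusted over the list alone, median 0.46, adjusted p = 0.00267, but adjusted p = 0.503 with an estimated correlation), which had no rise under library totals. Of 239 cytosolic tRNAs 9 rose and 27 fell, 35 adjusted over the list alone (median -0.07, camera adjusted p = 2.84e-08). It was at adjusted p = 0.000667 with an estimated correlation. Against the mitochondrial tRNAs alone, without the mc-tRNAs, it was at adjusted p = 0.000187, and at adjusted p = 0.04115 with an estimated correlation. The same comparison for the mitochondrial list was at camera adjusted p = 0.350 with an estimated correlation.

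R96C had 39 called tRNAs, 12 that rose and 27 that fell, with 71 at an unadjusted p under 0.05. Library totals gave 2 rises and 80 falls, DESeq2 size factors 21 rises and 25 falls, and leaving out reporter-alone replicate 2 gave 59 calls. Of the 25 named tRNAs 14 kept their call whichever library was left out. Calls were lost by mt-tRNA-Val-TAC and mt-tRNA-Leu-TAG (adjusted p = 0.253 each without mc-tRNA replicate 3), tRNA-Gln-CTG-3-1 (0.111 without it), and tRNA-Ser-AGA-3-1 and tRNA-Cys-GCA-4-1 (0.126 and 0.0574 without mc-tRNA replicate 2). They were also lost by tRNA-Pro-CGG-2-1 and tRNA-Pro-AGG-1-1 (0.0655 and 0.054 without mc-tRNA replicate 1) and mt-tRNA-Gln-TTG (0.074 without reporter-alone replicate 3). tRNA-Cys-GCA-8-1 and tRNA-Cys-GCA-3-1 lost theirs too (0.0835 and 0.224 without mc-tRNA replicate 2), as did tRNA-Leu-TAA-2-1 (0.0991 without mc-tRNA replicate 1). The share of other RNA was higher in the mc-tRNA libraries of this reporter (exact two-sided p = 0.3), and without the 3 libraries rich in it the count was 73, with 25 rises and 48 falls. Falls in R65 and R96C shared 9 tRNAs against 2.38 for independent lists (one-sided Fisher's exact test for an excess, adjusted p = 0.0022). This test takes references as independent, but the shared ones include tRNA-Arg-TCG-2-1, tRNA-Arg-TCG-4-1 and tRNA-Arg-TCG-5-1, which have the same anticodon. The inline barcode, which goes with the group in both pools, could also give shared falls. Of the 20 tests in this family 8 had an empty R96Q list and 6 an R96W list of 1 tRNA, so that few could pass. Falls shared 1 tRNA against 1.23 in R65 and R96H and 2 against 1.45 in R96C and R96H, and rises 1 against 0.368 in R65 and R96C (adjusted p = 1 each).

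In R96H the histidine tRNA with the anticodon of the mc-tRNA, tRNA-His-GTG-1-1, went from 4675 to 6269 CPM (log2 fold change 0.42, SE 0.15) and missed the threshold (adjusted p = 0.0598). Arginine tRNAs fell in 3 of 19 cases. These were tRNA-Arg-CCG-2-1 (9591 to 6404 CPM, -0.58, SE 0.16, adjusted p = 0.0253), tRNA-Arg-CCT-3-1 (-0.68, SE 0.19, adjusted p = 0.0308) and tRNA-Arg-CCT-1-1 (-0.53, SE 0.15, adjusted p = 0.0315). tRNA-Arg-CCT-2-1 (-0.51, adjusted p = 0.0598) and tRNA-Arg-CCG-1-1 (-0.40, adjusted p = 0.168) did not pass. The deepest falls were in serine tRNAs. tRNA-Ser-AGA-2-1 went from 1038 ± 288 to 416.7 ± 90.5 CPM (-1.32, SE 0.23, adjusted p = 0.000277) and tRNA-Ser-TGA-3-1 from 1115 to 477.8 CPM (-1.22, SE 0.24, adjusted p = 0.00117). In all, 8 of 18 serine tRNAs fell with none rising, 9 adjusted over the list alone (median -0.49, camera adjusted p = 5.24e-06). This call was lost at adjusted p = 0.588 with an estimated correlation.

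Rises were led by tRNA-Phe-GAA-1-1, from 2182 ± 172 to 6130 ± 3020 CPM (1.49, SE 0.33, adjusted p = 0.00655). Of 4 phenylalanine tRNAs 3 rose, 3 adjusted over the list alone (median 1.23, camera adjusted p = 0.028, but adjusted p = 0.588 with an estimated correlation). Of 8 tyrosine tRNAs 4 rose, 8 adjusted over the list alone (median 0.88, adjusted p = 0.0048, but adjusted p = 0.588 with an estimated correlation), among them tRNA-Tyr-GTA-1-1 from 871.5 to 1684 CPM (0.95, SE 0.29, adjusted p = 0.0364). tRNA-Met-CAT-5-1 rose by 0.80 (SE 0.20, adjusted p = 0.0185), the single methionine call of 7 (7 adjusted over the list alone, median 0.86, camera adjusted p = 0.00921, but adjusted p = 0.588 with an estimated correlation). tRNA-Ile-AAT-3-1 rose by 0.80 (SE 0.27, adjusted p = 0.0463), the single isoleucine call of 14 (7 adjusted over the list alone, median 0.76, camera adjusted p = 0.00323, but adjusted p = 0.588 with an estimated correlation). tRNA-Thr-TGT-1-1 rose by 0.86. The remaining named falls, tRNA-Ser-TGA-4-1, tRNA-Ser-TGA-1-1, tRNA-Ala-CGC-4-1, tRNA-Val-TAC-4-1, tRNA-Leu-AAG-4-1 and tRNA-Ser-CGA-4-1, ran from -0.85 to -0.63.

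The long variable arm list, which joins serine, leucine and selenocysteine tRNAs, had 9 falls and 1 rise among 37, 14 calls adjusted over the list alone and a median of -0.43 (camera adjusted p = 1.3e-06, but adjusted p = 0.588 with an estimated correlation). Arginine (median -0.33, adjusted p = 0.0117, 4 adjusted over the list alone) and leucine (1 rose and 1 fell of 18, 2 adjusted over the list alone, median -0.30, adjusted p = 0.0444) were also called, but both were at adjusted p = 0.588 with an estimated correlation. So were glutamine (no member called, 0 adjusted over the list alone, median 0.46, adjusted p = 0.0268) and mitochondrial tRNA (no member called, 0 adjusted over the list alone, median -0.28, adjusted p = 0.0169). These were at adjusted p = 0.588 with an estimated correlation as well.

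R96H had 32 called tRNAs, 18 rises and 14 falls, with 93 at an unadjusted p under 0.05, and the count rested on single libraries. It was 8, 6 and 6 without reporter-alone replicates 1, 2 and 3, 2 and 2 without mc-tRNA replicates 1 and 2, and 69 without mc-tRNA replicate 3. tRNA-Ser-AGA-2-1 and tRNA-Ser-TGA-3-1 alone of the 19 named tRNAs kept their call in all 6 of these fits. tRNA-Phe-GAA-1-1 missed the threshold without mc-tRNA replicates 1 and 2 (adjusted p = 0.064 and 0.0695). Library totals gave 14 rises and 27 falls, and DESeq2 size factors 48 rises and 21 falls. The fit without the 3 libraries rich in other RNA, none of them from R96H, gave 64 rises and 47 falls.

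In R96W, tRNA-His-GTG-1-1 rose from 4619 ± 690 to 7692 ± 1430 CPM (log2 fold change 0.74, SE 0.15, adjusted p = 0.0044), and the scarce tRNA-Lys-TTT-7-1 fell from 17.7 to 5.08 CPM (-2.12, SE 0.46, adjusted p = 0.00576). These were the 2 called tRNAs, and 36 had an unadjusted p under 0.05. A fit of the 6 R96W libraries alone called 0 (0.73 and -1.97, adjusted p = 0.993 for both). Tryptophan tRNAs with the anticodon of the mc-tRNA stood at 0.06 (tRNA-Trp-CCA-2-1, 14110 ± 7660 to 14720 ± 9830 CPM) and -0.25 (tRNA-Trp-CCA-4-1). The other 3 were at 0.22 (tRNA-Trp-CCA-1-1), 0.12 (tRNA-Trp-CCA-3-1) and 0.12 (tRNA-Trp-CCA-5-1), and the 5 adjusted p-values ran from 0.685 to 0.979. Arginine tRNAs stood at -0.50 (tRNA-Arg-TCG-5-1, adjusted p = 0.224), -0.36 (tRNA-Arg-TCG-2-1), -0.34 (tRNA-Arg-CCG-1-1), -0.26 (tRNA-Arg-CCT-1-1) and 0.33 (tRNA-Arg-TCT-1-1).

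Same-numbered replicates of R96W deviated together, so a fit with the replicate pairs as a block bears on this reporter. Blocked, tRNA-His-GTG-1-1 was called (0.73, adjusted p = 0.0247) and tRNA-Lys-TTT-7-1 was not (-2.03, adjusted p = 0.0749), which left 1 call. tRNA-His-GTG-1-1 lost its call without reporter-alone replicate 3 (adjusted p = 0.0531), and tRNA-Lys-TTT-7-1 without reporter-alone replicate 2 (0.0759) and without mc-tRNA replicate 1 (0.054). The count was 1 without reporter-alone replicate 3 and 8, 7 and 13 without mc-tRNA replicates 1, 2 and 3. Library totals gave 1 rise and 18 falls and DESeq2 size factors 7 rises and no fall. Without the 3 libraries rich in other RNA, 2 of which are of R96W, 6 tRNAs fell and none rose, and tRNA-His-GTG-1-1 was at 0.49 (adjusted p = 0.0949).

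For R96W 5 lists passed, at camera adjusted p = 0.049 each: arginine (median -0.13, 0 adjusted over the list alone), glutamine (0.45, 3 adjusted over the list alone), serine (-0.22, 0 adjusted over the list alone), and histidine and His-GTG, which hold the same single tRNA. The first 3 were at adjusted p = 0.816 with an estimated correlation, and a list of 1 has no such estimate. In the blocked fit, a choice made after the data were seen for lists, arginine and glutamine (0.012 each) and methionine and serine (0.025 each) were called and histidine was not. The single called list without the 3 libraries rich in other RNA was valine, downward (0.00497). For lists, the blocked fit and this one used the preset correlation only.

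Averaged over the 5 reporters, 71 endogenous tRNAs were called, 25 that rose and 46 that fell, with 105 at an unadjusted p under 0.05. Of them 43, 16 rises and 27 falls, had the same sign in each reporter. The 71 include tRNA-Ser-CGA-1-1 and tRNA-Ser-CGA-2-1, whose R65 counts hold mc-tRNA reads. Without these and tRNA-Ser-CGA-3-1 there were 69 calls with 23 rises. tRNA-Ser-CGA-4-1, with 15.8% of reads carrying the mc-tRNA base at position 35 in R65 with the mc-tRNA, was not taken out. The leading falls among these 43 were tRNA-Leu-TAA-4-1 (log2 fold change -0.85, SE 0.18, adjusted p = 0.00115), tRNA-Lys-TTT-6-1 (-0.81, SE 0.24, adjusted p = 0.0133) and tRNA-Leu-TAA-2-1 (-0.75, SE 0.12, adjusted p = 4.76e-05). Next were tRNA-Arg-CCG-1-1 (-0.57, SE 0.10, adjusted p = 7.22e-05), tRNA-Cys-GCA-18-1 (-0.56), tRNA-Arg-TCG-2-1 (-0.51, SE 0.08, adjusted p = 5.04e-05) and tRNA-Asn-GTT-9-1 (-0.46, SE 0.07, adjusted p = 2.68e-05). tRNA-Ser-AGA-4-1, tRNA-Ser-TGA-4-1 and tRNA-Val-TAC-4-1 fell by 0.44, 0.43 and 0.43 on the log2 scale. In R65 with the mc-tRNA, 17.9% of the reads on tRNA-Ser-TGA-4-1 carried the mc-tRNA base at position 35. The largest rise among these 43 was that of tRNA-Phe-GAA-1-1 (0.63, SE 0.15, adjusted p = 0.00263). Rises were also found for tRNA-Val-TAC-2-1 (0.51, SE 0.10, adjusted p = 0.000892), tRNA-Val-TAC-1-1 (0.46, SE 0.10, adjusted p = 0.0012) and tRNA-His-GTG-1-1 (0.41, SE 0.07, adjusted p = 7.22e-05). tRNA-Ile-AAT-6-1 (0.54), tRNA-Met-CAT-1-1 (0.38), tRNA-Gln-TTG-1-1 (0.37), tRNA-Gln-TTG-2-1 (0.36), tRNA-Thr-AGT-6-1 (0.32) and tRNA-Thr-AGT-5-1 (0.31) also rose. These 6 lost their call under library totals, with adjusted p from 0.0899 to 0.275.

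As families, 13 of 19 arginine tRNAs fell on average and none rose, 13 adjusted over the list alone (median -0.28, camera adjusted p = 3.20e-05, but adjusted p = 0.494 with an estimated correlation). Glutamine tRNAs rose in 6 of 11 cases and none fell, 7 adjusted over the list alone (median 0.30, camera adjusted p = 0.00242, but adjusted p = 0.724 with an estimated correlation). Under library totals no glutamine tRNA rose and the median was 0.13. The cytosolic list, with 24 rises and 45 falls among 239 and 69 adjusted over the list alone, had a median of -0.01 and an adjusted p of 0.00149, but adjusted p = 0.0722 with an estimated correlation. Against endogenous tRNAs only it was not called (adjusted p = 0.199), so the call came from the mc-tRNAs in its comparison set. Serine (2 rises, 8 falls, 12 adjusted over the list alone, adjusted p = 0.356) and phenylalanine (3 rises among 4, adjusted p = 0.0639) were not called. Against endogenous tRNAs only phenylalanine was at adjusted p = 0.02697, but at adjusted p = 0.6004 with an estimated correlation.

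Library totals turned the mean split to 9 rises and 90 falls and DESeq2 size factors to 53 rises and 43 falls. Leaving out R96W mc-tRNA replicate 3 gave 115 calls (49 rises, 66 falls), leaving out all 3 libraries rich in other RNA 142 (62 rises, 80 falls). Of the 20 named tRNAs 17 kept their call whichever of the 30 libraries was left out. tRNA-Ile-AAT-6-1 lost it in 20 of the 30 fits (adjusted p up to 0.104, without R96W mc-tRNA replicate 1). tRNA-Cys-GCA-18-1 lost it in 17 (up to 0.0929, without R96C mc-tRNA replicate 2) and tRNA-Met-CAT-1-1 in 4 (up to 0.0543, without R96H mc-tRNA replicate 1).

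**Figure D3:**
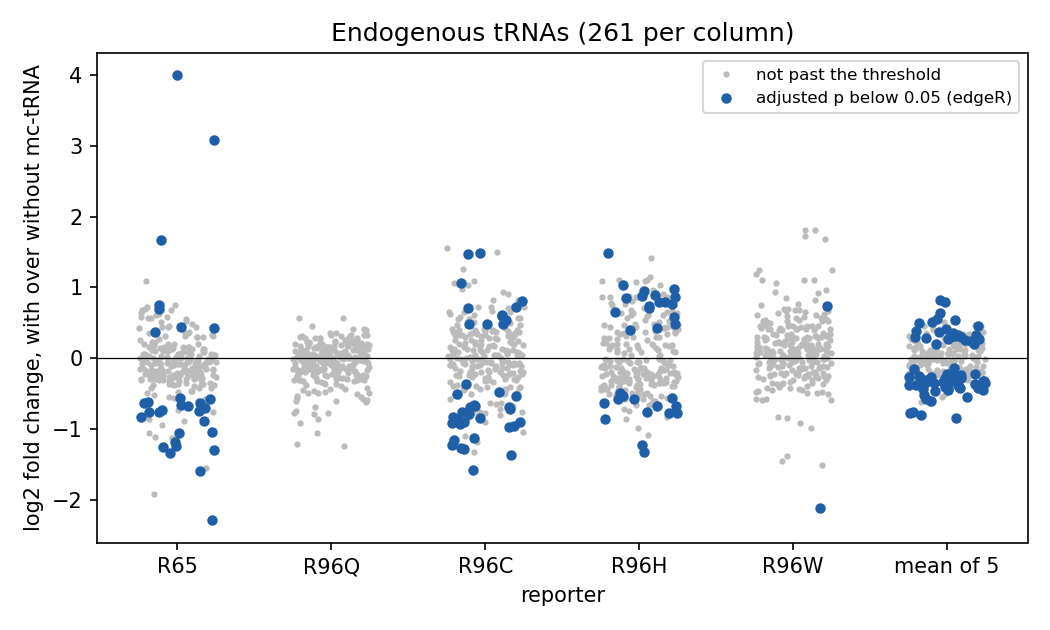
Log2 fold change (with the mc-tRNA over reporter alone, TMM scaling) of every endogenous tRNA in each reporter and in the mean, with called tRNAs coloured. R65 has 31 called tRNAs, R96Q 0, R96C 39, R96H 32, R96W 2 and the mean 71.

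A test of the difference among the 5 reporters called 19 endogenous tRNAs, with 60 at an unadjusted p under 0.05. Apart from the 3 tRNA-Ser-CGA references, whose R65 counts include reads with the sequence of the mc-tRNA, the smallest p was that of tRNA-Thr-CGT-1-1 (adjusted p = 0.000771), with log2 fold changes of -1.23 in R65, -0.02 in R96Q, -0.95 in R96C, 0.22 in R96H and -0.28 in R96W. tRNA-Ala-AGC-1-1 (adjusted p = 0.00170) was at -0.86 in R96C and between -0.20 and 0.48 elsewhere. tRNA-Ser-AGA-2-1 (adjusted p = 0.00359) was at -1.32 in R96H and 0.44 in R65. tRNA-Phe-GAA-3-1 (adjusted p = 0.0076) was at 1.48 in R96C and 0.98 in R96H, against -0.14 in R65 and -0.32 in R96Q. tRNA-Arg-TCG-5-1 (adjusted p = 0.0074) was at -1.16 in R96C and -0.67 in R65, against 0.10 in R96Q and 0.08 in R96H.

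The number of differing tRNAs was 11 to 12 without R65 reporter-alone replicates 1 or 2, R65 mc-tRNA replicates 2 or 3, R96H reporter-alone replicate 1 or R96H mc-tRNA replicate 2. It was 29 without R96H mc-tRNA replicate 3, 30 without R96W reporter-alone replicate 2, and 31 and 46 without R96W mc-tRNA replicates 1 and 3; without the 3 libraries rich in other RNA it was 80.

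The last comparison asked whether mismatch levels at 282 well-covered positions of the endogenous tRNAs changed. A fall or a rise below is of the mismatch level, tested as log2 odds with limma. In R65, 15 positions changed, 8 up and 7 down, with 44 at an unadjusted p under 0.05. C32 of tRNA-Ser-TGA-2-1 went from 97.9% ± 0.138 to 91.8% ± 2.28 (log2 odds -2.05, SE 0.19, adjusted p = 4.01e-08). C32 of tRNA-Ser-AGA-1-1 went from 94.1% ± 0.337 to 86.0% ± 2.69 (-1.36, SE 0.14, adjusted p = 1.45e-07). On these references the share of reads with the mc-tRNA base C at position 35 went up by 6.85 and 9.09 points, so the falls occurred on references that gained reads with the sequence of the mc-tRNA. A58 fell in tRNA-Gly-GCC-2-1 (94.8% to 90.3%, adjusted p = 0.00252), tRNA-Ala-TGC-3-1 (10.4% to 6.66%, adjusted p = 0.000318) and tRNA-Val-CAC-3-1 (74.3% to 64.1%, adjusted p = 0.0365). Mismatch rose at C32 of tRNA-Thr-TGT-2-1 (93.2% to 96.5%, adjusted p = 0.00632), the C at position 35 of tRNA-Thr-CGT-3-1 (39.0% to 53.4%, adjusted p = 0.010) and the C at position 24 of tRNA-Ala-AGC-1-1 (22.1% to 31.6%, adjusted p = 0.00433). It also rose at A37 of tRNA-Lys-TTT-3-1 (4.84% to 6.67%, adjusted p = 0.0348) and G6 of tRNA-Asp-GTC-2-1 (77.5% to 82.3%, adjusted p = 0.000652).

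Of the 106 A58 positions 1 rose and 5 fell in R65, 11 adjusted over the list alone (camera adjusted p = 5.95e-05, downward, but adjusted p = 0.979 with an estimated correlation). A remaining class held the 59 positions in no other class, among them position 34 with a base other than A. Of these 4 rose, 5 adjusted over the list alone (camera adjusted p = 2.08e-06, upward, but adjusted p = 0.143 with an estimated correlation). The R65 count was 7 and 8 without reporter-alone replicates 1 and 2 and 8 without mc-tRNA replicate 1. Of the 10 named positions 6 kept their call whichever library was left out. tRNA-Thr-TGT-2-1 (adjusted p = 0.077) and tRNA-Thr-CGT-3-1 (0.0881) lost it without reporter-alone replicate 1 among others, tRNA-Lys-TTT-3-1 in 4 of the 6 fits and tRNA-Val-CAC-3-1 in all 6.

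In the R96Q, R96C and R96W libraries with the mc-tRNA, mismatch fell at A58 of endogenous tRNA-Arg-CCT-4-1, the tRNA these mc-tRNAs were built from. It went from 94.1% ± 0.971 to 88.0% ± 1.99 in R96Q (log2 odds -1.12, SE 0.18, adjusted p = 0.00053) and from 94.1% ± 1.17 to 82.5% ± 3.25 in R96C (-1.76, SE 0.18, adjusted p = 1.07e-07). In R96W it went from 93.6% ± 1.24 to 89.1% ± 1.25 (-0.85, SE 0.18, adjusted p = 0.00694). In R96H it was at 95.1% and 92.7% and did not pass (-0.61, SE 0.18, adjusted p = 0.1496). In R96C, C32 of this tRNA also fell from 93.5% ± 1.38 to 81.9% ± 4.19 (-1.66, SE 0.34, adjusted p = 0.00149) and G9 from 33.2% to 27.3% (-0.42, SE 0.12, adjusted p = 0.0307). The call of G9 was lost in 5 of the 6 fits that left out 1 library (adjusted p up to 0.212, without mc-tRNA replicate 3). In the table of reads of 60 to 200 these last falls were not called (-0.42, adjusted p = 0.157, and -0.10, adjusted p = 0.471). Reads with A at position 34, which neither this tRNA nor an mc-tRNA carries, made up 0.806%, 15.7% and 2.69% of the reads on its reference in the 3 R96C libraries with the mc-tRNA, and up to 11.2% in those of R96W. In R96W mc-tRNA replicates 1 and 3 they made up 0.034% and 0.552%. The source of these reads was not tested, so the values of this reference there may not be those of the endogenous tRNA alone.

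R96Q had 3 changed positions, 1 up and 2 down, with 21 at an unadjusted p under 0.05. Beside tRNA-Arg-CCT-4-1, A58 of tRNA-Phe-GAA-1-1 fell from 28.8% ± 2.26 to 15.9% ± 3.32 (log2 odds -1.12, SE 0.21, adjusted p = 0.0032), and C32 of tRNA-Ser-TGA-2-1 rose from 97.5% to 98.6% (0.83, SE 0.19, adjusted p = 0.0175). The count was 5 without reporter-alone replicate 3 and 1 without mc-tRNA replicate 3, where tRNA-Phe-GAA-1-1 missed the threshold (adjusted p = 0.0586). tRNA-Ser-TGA-2-1 missed it in 4 of the 6 such fits (up to 0.204, without reporter-alone replicate 1). The variable-arm C of 2 serine tRNAs passed as a class (camera adjusted p = 0.00374, upward, 2 adjusted over the list alone), at adjusted p = 0.147 with an estimated correlation.

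R96C had 20 changed positions, 14 up and 6 down, with 44 at an unadjusted p under 0.05. The rises were led by A58 of tRNA-Tyr-GTA-4-1 (66.8% ± 2.47 to 83.3% ± 2.05, log2 odds 1.31, SE 0.12, adjusted p = 6.56e-08), tRNA-Val-TAC-2-1 (58.4% to 75.6%, adjusted p = 1.36e-06) and tRNA-Val-TAC-1-1 (58.2% to 74.99%, adjusted p = 1.07e-07). Mismatch also rose at A58 of tRNA-Gly-TCC-2-1 (92.3% to 95.5%, adjusted p = 0.000493) and at C32 of mt-tRNA-Thr-TGT, reference position 30 (51.0% to 67.7%, adjusted p = 0.0307). The adjusted p of the latter was 0.224 without mc-tRNA replicate 3, 0.14 without reporter-alone replicate 1 and 0.0947 without reporter-alone replicate 2. A58 fell in tRNA-Ser-GCT-5-1 (13.9% to 5.89%, adjusted p = 0.000358) and tRNA-Ala-AGC-3-1 (60.2% to 54.2%, adjusted p = 0.00208). As a class A58 had 8 rises and 3 falls among 106 and was not called (camera adjusted p = 0.902).

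R96H had no changed position. limma and the edgeR test both called 0, with 15 and 18 positions at an unadjusted p under 0.05. The smallest p-values belonged to position 34 of tRNA-Ser-TGA-2-1 (57.5% to 63.9%), A58 of tRNA-Tyr-GTA-4-1 (66.2% to 72.7%) and A58 of tRNA-Phe-GAA-1-1 (17.8% to 11.3%), each at adjusted p = 0.123. Leaving out mc-tRNA replicate 3 gave 2 calls, a fit of the 6 R96H libraries alone 8, and coverage minimums of 20 and 500 reads 5 and 1. R96W had 6, 3 up and 3 down, with 50 at an unadjusted p under 0.05. Beside tRNA-Arg-CCT-4-1, A58 rose in tRNA-Gly-TCC-1-1 (80.6% to 85.8%, adjusted p = 0.00272) and tRNA-Val-TAC-1-1 (55.7% to 63.4%, adjusted p = 0.0207) and fell in tRNA-Ala-AGC-3-1 (66.1% to 60%, adjusted p = 0.00618). Mismatch rose at G18 of tRNA-Ile-AAT-12-1 (9.02% to 12.8%, adjusted p = 0.00732) and fell at T34 of tRNA-Gln-TTG-3-1 (33.7% to 24.1%, adjusted p = 0.0384). A fit of the 6 R96W libraries alone called 0 positions. The R96W count was 12 without reporter-alone replicate 2, 12 without mc-tRNA replicate 1 and 28 without mc-tRNA replicate 3. tRNA-Val-TAC-1-1 missed the threshold without reporter-alone replicate 3 (adjusted p = 0.0889) and without mc-tRNA replicates 1 and 2 (0.0919 and 0.084). tRNA-Gln-TTG-3-1 missed it without reporter-alone replicates 1 and 2 (0.123 and 0.0713) and mc-tRNA replicate 3 (0.0564).

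Over the mean of the 5 reporters 35 positions changed, 26 up and 9 down, with 61 at an unadjusted p under 0.05. A58 rose in tRNA-Tyr-GTA-4-1 (69.0% to 75.4%, log2 odds 0.48, SE 0.05, adjusted p = 1.30e-06), tRNA-Val-TAC-1-1 (57.3% to 63.2%, adjusted p = 8.77e-06) and tRNA-Val-TAC-2-1 (58.4% to 64.1%, adjusted p = 0.000194). It fell in tRNA-Arg-CCT-4-1 (94.4% to 89.4%, log2 odds -0.88, SE 0.08, adjusted p = 3.16e-08) and tRNA-Ser-GCT-5-1 (12.9% to 9.50%, adjusted p = 0.00282), and in tRNA-Ala-TGC-4-1 (68.1% to 60.7%, adjusted p = 0.0194) and tRNA-Ala-TGC-5-1 (43.7% to 39.1%, adjusted p = 0.0376). C32 fell in tRNA-Arg-CCT-4-1 (93.9% to 88.6%, adjusted p = 0.000456) and rose in mt-tRNA-Thr-TGT (53.4% to 61.9%, adjusted p = 0.0106). Mismatch rose at position 35 of tRNA-Thr-CGT-3-1 (33.1% to 41.8%, adjusted p = 0.000194). Of the 59 positions of the remaining class 12 rose and 1 fell, 15 adjusted over the list alone (camera adjusted p = 0.00872), at adjusted p = 0.619 with an estimated correlation. Leaving out R96W mc-tRNA replicate 3 gave 59 changed positions. tRNA-Ala-TGC-5-1 lost its call in 17 of the 30 fits that left out 1 library (adjusted p up to 0.0666, without R65 mc-tRNA replicate 2). Without the 3 libraries rich in other RNA the counts of changed positions were 45 in R65, 9 in R96Q, 44 in R96C, 2 in R96H, 35 in R96W and 85 in the mean.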

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

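Of the tests in this part, those of own-base reads on the tRNA-Ser-CGA references, of mc-tRNA amount, of alignment loss and of the mismatching base at C32 were chosen only after the result was seen.

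The effect of the mc-tRNA differed among the 5 reporters, by the F-test in edgeR, for 19 references of endogenous tRNAs. The 3 tRNA-Ser-CGA references among them are no evidence of a difference in endogenous tRNAs, since 72.7% to 82.1% of their reads in R65 with the mc-tRNA carried its base at position 35. Serine tRNAs were tRNA-Ser-CGA-1-1 (adjusted p = 9.47e-15), tRNA-Ser-CGA-2-1 (1.59e-09), tRNA-Ser-CGA-3-1 (0.0162), tRNA-Ser-AGA-2-1, tRNA-Ser-TGA-1-1 (0.00359 each) and tRNA-Ser-TGA-3-1 (0.00467), the last at 0.53 in R65 and -1.22 in R96H on the log2 scale. Alanine tRNAs were tRNA-Ala-AGC-1-1 (0.001705), tRNA-Ala-AGC-13-1 (0.02495), tRNA-Ala-AGC-10-1 (0.0282) and tRNA-Ala-AGC-12-1 (0.0340). Arginine tRNAs were tRNA-Arg-TCG-5-1 (0.0074), tRNA-Arg-TCG-4-1 (0.0340) and tRNA-Arg-TCG-2-1 (0.0439), and phenylalanine tRNAs were tRNA-Phe-GAA-3-1 (0.0076) and tRNA-Phe-GAA-2-1 (0.0107). The others were tRNA-Thr-CGT-1-1 (0.000771), tRNA-Asn-GTT-9-1 (0.00359, at -1.18 in R65 and -0.67 in R96C), tRNA-Lys-TTT-1-1 (0.0388, at -0.73 in R65 and 0.67 in R96W) and tRNA-Leu-TAA-3-1 (0.0408). Of 100 drawn splits of the libraries within reporters, 6 gave as many differing tRNAs as the real 19, with a highest other of 44, so chance is not excluded for this count.

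In reporter-alone libraries each mc-tRNA reference held more of the tRNA counts in its own reporter than in the 12 reporter-alone libraries of the others: 0.0465% against 0.000596% for mc-Ser-tRNA_Arg(CCG), 0.743% against 0.00701% for mc-Arg-tRNA_Gln(CTG), 0.258% against 0.00922% for mc-Arg-tRNA_Cys(GCA), 0.118% against 0.00772% for mc-Arg-tRNA_His(GTG) and 0.824% against 0.0113% for mc-Arg-tRNA_Trp(CCA).

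In R65 the serine references that share the mc-tRNA body gained counts, with a median log2 change of 3.09 over tRNA-Ser-CGA-1-1, tRNA-Ser-CGA-2-1 and tRNA-Ser-CGA-3-1. Reads with their own base at position 35, as a share of tRNA counts, changed by a median of -0.132 on the log2 scale. This argues for mc-tRNA reads counted on these references and against a rise of the endogenous tRNAs as a group, though tRNA-Ser-CGA-1-1 alone, at 0.76, leaves a smaller rise open. The lower C32 mismatch of tRNA-Ser-TGA-2-1 and tRNA-Ser-AGA-1-1 may have the same source, since reads with the mc-tRNA base went up there by 6.85 and 9.09 points and C32 mismatch down by 6.15 and 8.08 points, a lowest ratio of 1.113. Of the 10 splits of the R65 libraries, too few for a share under 0.05, only 1, the real one, reached its 31 tRNAs and 1 its 15 positions, and the highest others had 0 and 0.

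C32 mismatch was low in the 4 mc-tRNAs built on tRNA-Arg-CCT-4-1. Limiting capacity alone would leave alike amounts of modified mc-tRNA, but they ran from 470.1 ± 15.8 CPM in R96Q to 4803 ± 436 CPM in R96H, a ratio of 10.2 that argues against amount as the only cause. A loss of heavily mismatched reads in alignment was not seen at A58, where each mc-tRNA lay above tRNA-Arg-CCT-4-1 of the reporter-alone libraries, by 0.539 points at the least. At G7, however, the differences from the same parent values were -12.2, -10.2, -15.5 and -16.6 points in R96Q, R96C, R96H and R96W. The sites differ, so such a loss stays open. A changed anticodon, which removes T36, may lower C32 modification. Serine tRNAs go against a need for T36, as 11 of 12 with A36 stood at 10% or more, with a median of 88.5%. Outside serine, 82 of the 84 endogenous tRNAs without T36 stood below 10%, against 25 of 74 with T36 at 10% or more. The other 2, tRNA-Arg-TCG-6-1 (55.0% of 347 reads) and tRNA-Asp-GTC-3-1 (10.6% of 9593 reads), were set to count against a need for T36. They had 100% and 46.2% of their mismatches on 1 base, outside the 72.2% to 90.9% of the 42 other tRNAs at 10% or more. They therefore decide nothing. mc-Ser-tRNA_Arg(CCG) was not part of these tests. Its C32 and variable-arm C at position 50 stood at 14.2% and 38.1%, against 83.6% and 89.1% in the reporter-alone parent. Its G26 and A58 stood at 84.2% and 59.0%, against 86.15% and 43.5%. Lower mismatch was thus also seen outside the anticodon loop, as at G7, where a changed anticodon was not tested. The anticodon stays open as a hypothesis, and the amount of mc-tRNA as a contributing cause.

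In the mean of the 5 reporters 71 tRNAs were called, or 69 without tRNA-Ser-CGA-1-1, tRNA-Ser-CGA-2-1 and tRNA-Ser-CGA-3-1. Of the 71, 43 had the same sign in each reporter. A call in the mean can rest on a single reporter, so the 71 do not measure a shift shared by all 5. Short fragments are argued against as the source of these calls, since 68 of the 71, or 95.8%, kept their direction and call in the 60 to 200 counts. An inline barcode that always goes with the mc-tRNA group could give the same changes. tRNAs called from the other reporters had slopes of 0.31, 0.38, 0.95, 0.74 and 0.34 in the reporter left out. Their median of 0.377 lies between the values set for and against the barcode. A response common to the mc-tRNAs would give such slopes too, so no slope could decide between them. Barcode and mc-tRNA cannot be told apart because the barcode goes with the group in every pool. Of 100 drawn splits within reporters, 1, the real one, reached 71 calls (highest other 29), and 1, the real one, reached 35 positions (highest other 19). The smallest share that 100 splits allow is 1 in 100, so this argues against chance for these counts but does not exclude it. The 3 called lists were reached by 95 splits (highest other 16), which leaves chance open for them. A response to the mc-tRNAs stays open beside the barcode, as untested.

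For single reporters the 10 splits are too few for a share under 0.05. The counts of splits as large, the real value and the highest other were 10, 0 and 0 for tRNAs in R96Q, 1, 39 and 19 in R96C, 1, 32 and 0 in R96H, and 7, 2 and 90 in R96W. For positions they were 1, 3 and 0 in R96Q, 1, 20 and 1 in R96C, 10, 0 and 0 in R96H, and 5, 6 and 98 in R96W. For lists they were 5, 6 and 9 in R65, 10, 0 and 8 in R96Q, 3, 10 and 13 in R96C, 4, 10 and 12 in R96H, and 9, 5 and 12 in R96W.

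The R96W split with 90 tRNAs and 98 positions sets reporter-alone replicates 1 and 3 and mc-tRNA replicate 3 against the rest, which points to a structure of the samples other than the groups. These libraries had 11.8%, 40.3% and 46.3% of counts on other RNA. Reporter-alone replicate 2 and mc-tRNA replicates 1 and 2 had 7.11%, 3.29% and 6.315%. Among the 4 R96W splits that part all 3 pairs the highest others were 4 tRNAs, 5 positions and 10 lists; the 6 that keep a pair together reached 90 and 98. The R96C split with 19 tRNAs sets reporter-alone replicates 1 and 3 and mc-tRNA replicate 2, with 6.09%, 4.59% and 4.60% of counts on other RNA, against the libraries with 9.74%, 13.4% and 18.7%.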

How the results depend on the processing

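Fits without the 3 libraries with over 15% non-tRNA counts, the parent tRNA taken from reporter-alone libraries, the replicate block for lists and lists against endogenous tRNAs only were chosen after the data were seen; the other settings were fixed before. In the settings below, the cause was not tested, unless stated. Depth limits tRNAs such as tRNA-Lys-TTT-7-1, at 17.7 CPM or less, and parent positions with few reads.

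Counts of called tRNAs that moved by more than 1.5 times were as follows. DESeq2 gave 69 in R96H, 7 in R96W and 51 for the difference among reporters, and library totals 3 in R96Q, 82 in R96C, 19 in R96W and 48 for the difference. No filter gave 20 in R96H, a mean of at least 100 counts 57, and the 60 to 200 counts 53 in R96H, 4 in R96W and 36 for the difference. Leaving out the mc-tRNA and its body gave 12 for the difference. Sums per anticodon, with fewer features tested and their own scaling factors, gave 3 in R65, 14 in R96C, 17 in R96H, 1 in R96W, 17 in the mean and 2 for the difference. The 6 libraries of a reporter alone gave 68 in R65, 92 in R96H and 0 in R96W. Without the 3 libraries rich in other RNA the counts were 53 in R65, 73 in R96C, 111 in R96H, 6 in R96W, 142 in the mean and 80 for the difference.

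With the replicate block the count was 57 in R96H and 1 in R96W. Deviations of same-numbered libraries correlated at -0.06, -0.11 and 0.23 in R96H and at 0.36, 0.28 and 0.57 in R96W. The labels state no pairs, so a pairing of samples in R96W is not established. Positions in R65 numbered 9 and called lists in the mean 9. The block changed no other count by more than 1.5 times (abundance 34, 0, 40, 83 and 15 in R65, R96Q, R96C, the mean and the difference). Over the 15 same-numbered pairs 5 correlated above 0.1, from -0.38 to 0.57, and 4 libraries correlated best with their own number.

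The log2 ratio of mc-tRNA anticodon reads kept the direction of the mc-tRNA level, at 0.45, 0.71, 1.53, 2.58 and 0.82 in R65, R96Q, R96C, R96H and R96W, with a test that cannot pass the threshold.

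Changed positions numbered 29 in R65, 5 in R96H and 66 in the mean with 20 reads, and 10 in R96C, 1 in R96H, 2 in R96W and 18 in the mean with 500. A mismatch minimum of 5% and edgeR each gave 24 in R65, and R96Q had 6 in the 60 to 200 tables. The 6 libraries of a reporter alone gave 32, 0, 11, 8 and 0 in R65, R96Q, R96C, R96H and R96W. Without the 3 libraries rich in other RNA they were 45, 9, 44, 2, 35 and 85 in R65, R96Q, R96C, R96H, R96W and the mean.

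Called lists fell to 1 in R65, 1 in R96C, 0 in R96H, 0 in R96W and 0 in the mean with an estimated correlation. The 60 to 200 counts gave 2 in R96Q, 6 in R96H and 3 in R96W. Without the 3 libraries rich in other RNA R96W had 1 and the mean 9. Against endogenous tRNAs only R96Q had 2 and the mean 6.

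The median mismatch difference between mc-tRNA and parent turned sign in R96C with 500 reads (-34.6), in the 60 to 200 tables (-6.76), against the reporter-alone parent (-4.76) and without mc-tRNA replicate 3 (-0.032), and in R65 against the reporter-alone parent (-26.5). The minimum of 500 reads dropped G7 and A58 in R96C, where the parent had lowest coverages of 361 and 471. The median there is that of G9 (12.1) and C32 (-81.3) alone, at unchanged mismatch levels. It moved to -6.99 and -7.50 in R96H with the 60 to 200 tables and the reporter-alone parent, and with the 60 to 200 tables to -9.01 in R96Q and -11.8 in R96W.

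With 1 library left out, called tRNAs ranged from 19 to 27 in R65, 0 to 0 in R96Q, 26 to 59 in R96C, 2 to 69 in R96H, 1 to 13 in R96W, 61 to 115 in the mean and 11 to 46 for the difference. Positions ranged from 7 to 12, 1 to 5, 14 to 22, 0 to 2, 5 to 28 and 31 to 59 in R65, R96Q, R96C, R96H, R96W and the mean. The mc-tRNA log2 fold change ranged from 7.32 to 7.56, 3.85 to 4.68, 6.16 to 6.55, 5.27 to 5.63 and 4.06 to 4.76 in R65, R96Q, R96C, R96H and R96W, and the median mismatch difference from 6.00 to 6.98, -6.94 to -5.01, -0.032 to 2.81, -6.25 to -5.42 and -8.77 to -4.86.

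Of the values of single named tRNAs under left-out libraries, 973 kept their direction and side of the threshold, 168 lost the call, 2 gained it and 9 uncalled ones changed sign; under other settings these were 978, 52, 29 and 9. For named positions they were 440, 50 and 2, and 307, 25 and 3, with no change of sign.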

Other observations

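The 3′ end, the A at position 34 and the mc-tRNA references in other reporters named here were picked after their values were seen. The test of read lengths was also chosen only after the result was seen. The other tests below were set beforehand, unless stated.

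The last A of the 3′ end was covered in 51.5% ± 2.64 of mc-Arg-tRNA_Gln(CTG) reads (SD, n = 3) and 69.4% ± 1.29 of tRNA-Arg-CCT-4-1 reads in the same libraries. For mc-Arg-tRNA_His(GTG) the values were 58.6% ± 7.69 and 67.4% ± 2.93, and for mc-Arg-tRNA_Trp(CCA) 52.4% ± 13.3 and 68.8% ± 5.83. For mc-Ser-tRNA_Arg(CCG) and the tRNA-Ser-CGA-1-1 reference, which holds mostly mc-tRNA reads there, they were 69.2% ± 1.21 and 69.7% ± 1.20. mc-Arg-tRNA_Cys(GCA) stood at 51.1% ± 2.32, where the median cytosolic tRNA was at 56.2%.

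Reads with A at position 34 of tRNA-Arg-CCT-4-1 made up 15.7% of 6958 reads in R96C mc-tRNA replicate 2, and 11.2% in R96W mc-tRNA replicate 2. They made up 4.29% in R96H mc-tRNA replicate 2, 1.53% in R96Q mc-tRNA replicate 2 and 2.69% in R96C mc-tRNA replicate 3. The other 7 libraries with an arginine-bodied mc-tRNA had 0.017% to 0.806%, and the 12 reporter-alone libraries of these reporters 0.056% to 0.651%. The mc-Arg-tRNA_Trp(CCA) reference held 0.816%, 0.847% and 0.822% of tRNA counts in the 3 R96C libraries with mc-Arg-tRNA_Cys(GCA). mc-Arg-tRNA_Gln(CTG) held 0.320%, 0.315% and 0.364% in the 3 R96H libraries with mc-Arg-tRNA_His(GTG).

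In R96C, 5.8S and 5S rRNA made up 2.66% and 2.12% of counts without and 5.53% and 4.28% with the mc-tRNA (exact two-sided p = 0.4 and 0.3). The lists that passed in none of the 6 contrasts had lowest camera adjusted p-values of 0.345 for initiator methionine, 0.253 for selenocysteine, 0.132 for A at position 34 and 0.291 for aspartate. The values were 0.164 for glutamate, 0.470 for glycine, 0.413 for lysine, 0.114 for threonine, 0.0586 for tryptophan and Trp-CCA, and 0.208 for valine. Against endogenous tRNAs only, a comparison chosen after the data were seen, A at position 34 (0.0406) and tryptophan and Trp-CCA (0.02995) passed in R96H, but were at adjusted p = 0.4895 with an estimated correlation. Threonine passed in R96W (0.0345), but was at adjusted p = 0.701 with an estimated correlation. In R96H all 5 Trp-CCA tRNAs passed adjusted over the list alone, with a median of 0.87.

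By their deposited names the 6 libraries of a reporter share a pool, and the mc-tRNA counts of reporter-alone libraries could be reads passed on from the libraries with the mc-tRNA. As the only source, with lengths unchanged, this is argued against by the 60 to 200 tables. In each reporter every reporter-alone library kept a smaller percent of its mc-tRNA counts there than every library with the mc-tRNA, the ratio of the highest to the lowest being 0.503 or less. All tRNA counts of the same reporter-alone libraries kept 89.8% to 98.6%. A passage that favours short reads, a passage of the 60 to 200 reads and mc-tRNA in the reporter-alone cells stay open.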
